A study of Rattus norvegicus with 119 samples.

How the data were processed

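Gene expression in scraped bladder urothelium of Sprague-Dawley rats was measured on 119 one-colour (Cy3) Agilent arrays, 1 animal per array. The animals had been dosed by mouth once a day for 3, 28 or 90 days with methylcellulose vehicle, with rosiglitazone (10 mg/kg/day) or with pioglitazone at a low (16) or a high (63 mg/kg/day) dose. Tissue was taken 1 day after the last dose. Sex, treatment and dosing time give 24 groups, which hold 4 or 5 arrays each after 3 arrays that the submitters marked as failing quality control were left out. The arrays left out were high-dose pioglitazone female day 3 replicate 2, low-dose pioglitazone male day 90 replicate 5 and high-dose pioglitazone male day 3 replicate 5. The 116 arrays used comprise 30 vehicle arrays, 28 of 29 with low-dose pioglitazone, 28 of 30 with high-dose pioglitazone and 30 with rosiglitazone.

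The deposited values are log2 signals that the authors had already normalised. The submitters' processing notes name limma, without a version or what it was used for. The method of background correction and normalisation is not given in the sources used here, and it stays unknown beyond what the values show. On the arrays used, the column medians lie between 6.4 and 6.63 and the 75th percentiles between 9.35 and 9.60. Of all arrays in the values, 101 share the same maximum of 18.98. Among them is the failing array of high-dose pioglitazone female day 3 replicate 2, whose median is 7.30. The shared maximum therefore does not show that the arrays share a distribution. The values are not centred per gene, so a difference of group means is treated minus vehicle on the log2 scale, and its direction is known. For arrays the number of animals limits the precision. The p-values of single genes measure the spread between these animals. Those of gene lists compare a list with the other genes, under an assumed or an estimated correlation between genes.

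The value table holds 30367 probes, of which 20369 carry 1 gene symbol, 0 carry several and 9998 carry none. Symbols were brought up to date through RefSeq accessions, which matched 17245 probes and changed 2887 symbols. The probes stand for 16951 genes, 3091 of them with more than 1 probe. Each gene was represented by its probe with the highest mean over the arrays. Genes in the lowest 25 percent of mean signal were left out (those with a mean log2 signal under 5.31), leaving 12713 genes for testing. Genome positions were not analysed here.

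A linear model with 1 mean per group was fitted to the 116 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend on mean signal, 92 residual and 3.96 prior degrees of freedom). The contrasts were each treatment against vehicle as the mean over both sexes and 3 dosing times, each treatment within each sex and time, the difference of the effect between sexes and across times, the differences between treatments, and females against males among vehicle animals. The difference across times is an F test of the effects at 3, 28 and 90 days, each averaged over the sexes. The p-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. Intervals are 95 percent confidence intervals. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

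For 20 gene lists, camera (limma) compared each list with the other tested genes, with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals. The p-values were adjusted over the lists within a contrast. The lists are PPAR-gamma targets and lipid droplet genes, fatty acid oxidation, fatty acid and sterol synthesis, oxidative phosphorylation, oxidative stress and xenobiotic metabolism, umbrella cell and urothelial differentiation, basal urothelial markers, squamous differentiation, cell cycle and mitosis, immediate-early and EGFR ligand genes, inflammatory mediators, p53 targets and DNA damage, water and ion transport, and markers of adipocytes, smooth muscle, fibroblasts and matrix, endothelium, leukocytes, skeletal muscle and erythrocytes. They share 5 genes: Cidec, Lipe and Plin1 stand in the PPAR-gamma and adipocyte lists, Aqp7 in the PPAR-gamma and water transport lists, and Slc4a1 in the erythrocyte and water transport lists. Which of the marker genes urothelial cells also express is not given in the sources used here.

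Genes were named by a fixed rule. For each treatment the rule takes up to 10 genes with the largest rise and up to 10 with the largest fall among called genes with the same sign in all 6 combinations of sex and time. It adds up to 4 members of each list with the smallest adjusted p, the 5 genes with the largest difference in each direction for the other differences (the 8 smallest p for F tests), and the drug target Pparg with its partner Rxra. Predicted loci with no name were passed over. Genes of a list that are named outside the rule were chosen after their values were seen; these are Aldh1a1, Adipor2, Cd14, Cd3d, Por and Gclc and, in the closing section, Cyp1b1, Nqo1 and Ugt1a6. Nfe2l2, Sbp, Pbsn and Svs4 come from short lists made for the closing tests. Values of rule genes in treatments for which the rule did not take them are given for comparison. Calls of such values and of genes named outside the rule were not checked with a replicate number left out. The comparisons, the tests, the lists, the naming rule and most of the alternatives were fixed before the data were examined.

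The same fit was tested on simulated data with 200 changed genes. For high-dose pioglitazone over both sexes and all times it recovered 73 percent of changes of 0.5 log2 and 96 percent of changes of 1 log2, with 9 false calls among 178. For a single sex and time (high-dose males at 28 days) it recovered 7 percent and 51 percent, with 2 false calls among 60. The simulated genes varied independently of each other, with the same spread on every array. The rates of false calls therefore need not hold for the real arrays.

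Because the 3 treatments share vehicle animals, correlations between treatments were set beside 100 simulations of unchanged groups sharing those animals, and correlations and overlaps beside 20 random splits of the vehicle animals between the treatments compared. Simulated overlaps are not used, since unchanged groups give almost no calls. Alternatives were the 3 failing arrays included, no filter on low signal, quantile normalisation on top of the deposited values, centring of each array on its 75th percentile, the mean of a gene's probes, the replicate number within sex and time as a block, only the compared groups in the fit, and each replicate number of a treatment left out in turn. After the data had been seen, 2 more were added: without the 2 arrays whose median correlation with their own group was under 0.9, and with each array's smooth muscle marker score as a covariate. For each count of genes, 100 splits of the animals were also drawn, the real one included.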

Results

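The bladder lining of male and female rats was profiled after repeated dosing with pioglitazone or rosiglitazone, a pair of thiazolidinediones that lower blood glucose by activating the nuclear receptor PPAR-gamma. Urothelium scraped from the opened bladder was hybridised to 1 array per animal after 3, 28 or 90 daily doses. Low-dose pioglitazone is 16 mg/kg/day, high-dose pioglitazone is 63 mg/kg/day, and rosiglitazone was given at 10 mg/kg/day. The comparisons used 30 vehicle arrays, 28 with each pioglitazone dose and 30 with rosiglitazone, in 24 groups of 4 or 5 animals. The median log2 signal per array was 6.4 to 6.63 over 30367 probes. The median array correlated with the others at 0.980 across probes. Means of a treatment are over both sexes and all 3 times, with SE from the fit and SD within groups.

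Compared with vehicle, all 3 treatments raised Fabp4, Acaa1a and Cpt1c, single genes of fatty acid handling. Fabp4, which carries fatty acids inside cells, had a vehicle mean of 14.16 (log2 signal, SD 0.59, n = 30) and rose 1.98-fold, 2.33-fold and 2.1-fold with low-dose pioglitazone, high-dose pioglitazone and rosiglitazone, in that order. Acaa1a, a peroxisomal thiolase of fatty acid oxidation, had a vehicle mean of 14.32 (SD 0.38, n = 30) and rose 2.38-fold, 2.71-fold and 2.49-fold. Cpt1c, a member of the carnitine palmitoyltransferase family, rose by 1.43 ± 0.12, 1.68 ± 0.12 and 1.64 ± 0.12 (log2, SE). For Fabp4, Acaa1a and Cpt1c the difference was positive in 6 of 6 combinations of sex and time with each treatment. Their adjusted p-values were at most 3.77e-07. The probe of Acaa1b, whose sequence is close to that of Acaa1a, gave 1.25, 1.44 and 1.37.

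The largest rises also took in genes with other known roles. Rgs17, a regulator of G-protein signalling, had a vehicle mean of 6.50 (SD 0.50, n = 30) and rose 2.99-fold, 3.52-fold and 3.34-fold with low-dose pioglitazone, high-dose pioglitazone and rosiglitazone. Akr1b8, an aldo-keto reductase, rose 3.55-fold, 3.35-fold and 3.26-fold (adjusted p 0.000121, 0.000105 and 0.000124). Its difference was positive in 6, 6 and 5 of the 6 combinations. Ttr, a carrier of thyroid hormone and of retinol-binding protein, rose by 1.34, 1.44 and 1.58 log2, and Rbp7, a retinoid-binding protein, by 1.11, 1.43 and 1.40. Ces2c, a carboxylesterase, rose by 1.28, 1.25 and 1.29. Tuba8, an alpha-tubulin, gave 1.26, 1.44 and 0.97. Mmp24, a membrane-bound metalloproteinase, gave 1.01, 1.40 and 1.20, and Gabbr1, a subunit of the GABA-B receptor, 0.85, 1.25 and 1.11. Gkn1 and Gkn2, secreted proteins best known from the stomach lining, were higher by 0.88, 0.85 and 1.12 and by 0.81, 0.67 and 1.14. All of these values passed the test, the highest adjusted p being 0.0327 for Gkn2 with high-dose pioglitazone.

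Among the genes that fell, Krt4, a keratin of moist stratified epithelia, had a vehicle mean of 12.22 (SD 0.80, n = 30) and was 1.93-fold, 3.05-fold and 2.13-fold lower with low-dose pioglitazone, high-dose pioglitazone and rosiglitazone (adjusted p 0.00769, 9.49e-08 and 0.000345). The transcription factor genes Pou3f1 and Tbx1 gave -1.04, -1.14 and -1.12 and -0.93, -1.07 and -1.03. Apoe, a lipoprotein component, gave -0.85, -0.91 and -1.05, and Gpt, alanine aminotransferase, -0.81, -0.94 and -0.88. Pigr, which carries immunoglobulins across epithelia, gave -0.53, -0.93 and -0.82. The intracellular chloride channel gene Clic3 gave -0.68, -1.14 and -0.80, and S100a1, a calcium-binding protein, -0.72, -0.84 and -0.81. Rpesp, Cracr2b, Tspan11, Cdh13 and Ust also fell with each treatment, with log2 differences from -0.48 for Ust with low-dose pioglitazone to -1.39 for Rpesp with high-dose pioglitazone. From Pou3f1 to Ust every one of these values passed the test. Plac9 (-0.86), Crip1 (-0.87) and Anxa1 (-0.73) fell with low-dose pioglitazone, and Plac9 with rosiglitazone too (-0.93). Hsd11b2, which inactivates glucocorticoids, gave -0.37, -0.67 and -0.94 and was called with rosiglitazone, at an adjusted p of 0.0132, but not without vehicle replicate 1 (0.0728) or rosiglitazone replicate 4 (0.0607). Cabcoco1 gave -0.65 with high-dose pioglitazone and -0.94 with rosiglitazone. Without low-dose replicate 1 the low-dose calls of Krt4, Cdh13, Plac9, Crip1 and Anxa1 ended, at adjusted p 0.058, 0.0557, 0.0963, 0.142 and 0.108. Low-dose replicates 3 and 4 also ended those of Plac9 (0.123 and 0.0965), Crip1 (0.115 and 0.176) and Anxa1 (0.0932 and 0.0951). Vehicle replicates did so for Plac9 (0.0652, 0.0691 and 0.0718 without 1, 3 and 5), Crip1 (0.0946, 0.0717 and 0.0645 without 3, 4 and 5) and Anxa1 (0.0997 without 3).

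**Figure D1:**
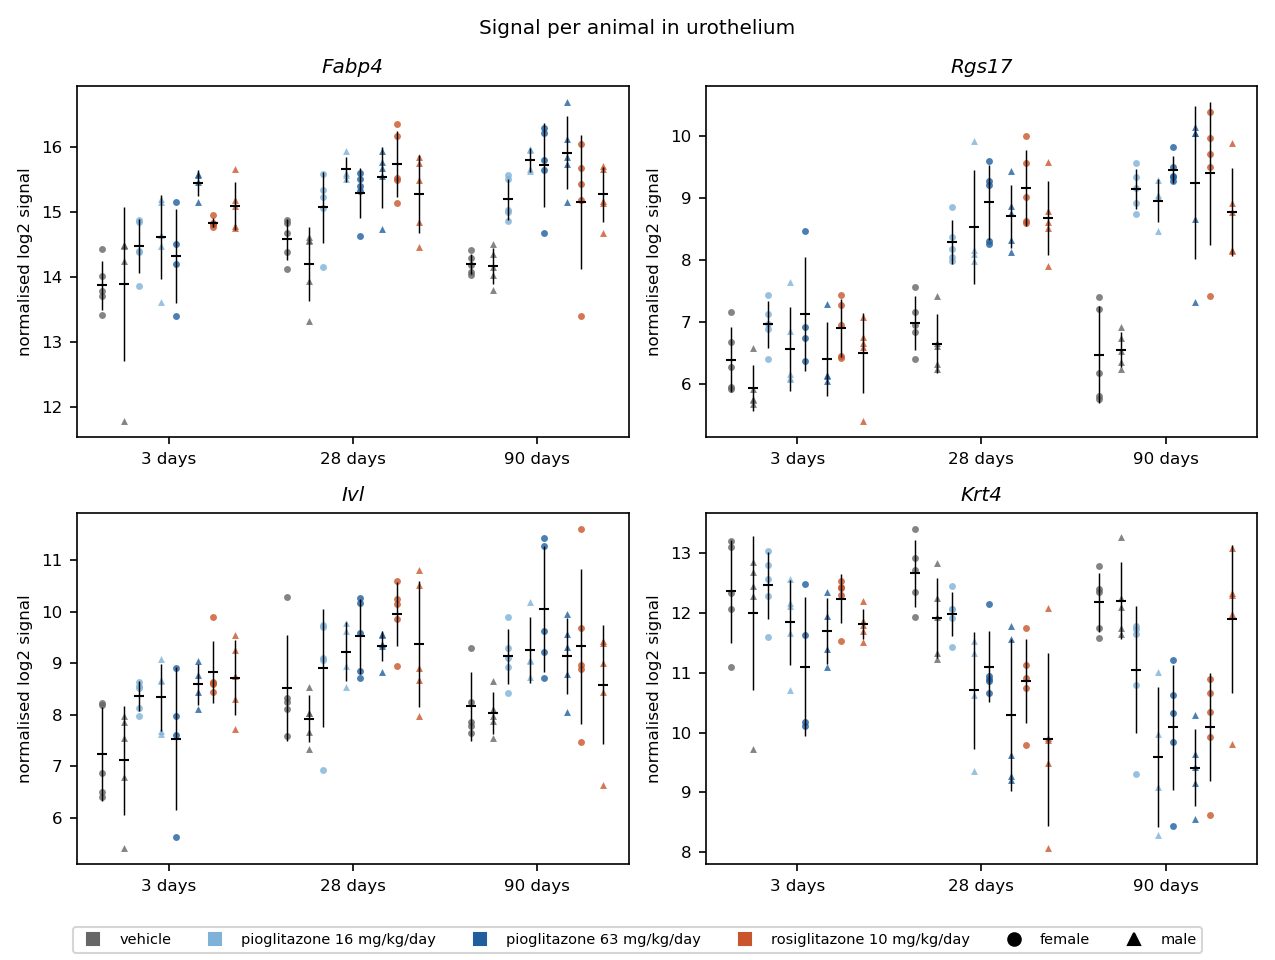
Normalised log2 signal of Fabp4, Rgs17, Ivl and Krt4 in each animal by dosing time, coloured by treatment, with circles for females and triangles for males and black marks for the mean ± SD of each group. The Rgs17 difference of high-dose pioglitazone from vehicle, averaged over the sexes, was 0.60 at 3 days, 2.0 at 28 days and 2.84 at 90 days.

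Of the 24 tested PPAR-gamma targets and lipid droplet genes, 5, 6 and 5 rose and 0, 1 and 0 fell with low-dose pioglitazone, high-dose pioglitazone and rosiglitazone. Adjusted over the list alone, 5, 14 and 8 rose and 0, 1 and 1 fell. Besides Fabp4, Plin2, which coats lipid droplets, rose by 0.57, 0.80 and 0.68, and Angptl4, an inhibitor of lipoprotein lipase, by 0.41, 0.46 and 0.50. Fabp5 rose by 0.50, 0.52 and 0.44, its low-dose call ending without low-dose replicate 1, 3 or 4 (adjusted p 0.131, 0.0643 and 0.12) or vehicle replicate 1 or 2 (0.0699 and 0.0573). Gpihbp1, the capillary anchor of lipoprotein lipase, rose by 0.81 with high-dose pioglitazone and 0.81 with rosiglitazone, and its low-dose value was 0.32 (adjusted p 0.267). Fabp3 rose by 0.98 with high-dose pioglitazone, and Adipor2 fell by 0.21 (adjusted p 0.0492). The Adipor2 call ended with quantile normalisation, with the replicate block, with the failing arrays included and without the 2 arrays of low correlation. The list mean was 0.13, 0.48 and 0.27 log2, with a camera adjusted p of 0.0119, 5.9e-11 and 6.51e-05. With an estimated correlation the adjusted p was 0.568, 0.0322 and 0.386, so the high-dose call held. In the same treatment the means of adipocyte markers (0.44, adjusted p 0.0233), which share Cidec, Lipe and Plin1 with this list, and of smooth muscle markers (0.38, adjusted p 0.199) were also above 0. The adipocyte call was lost with an estimated correlation. Whether adipose tissue in the scrapings adds to the mean of the PPAR-gamma list was not tested. The receptor gene itself, Pparg, had a vehicle mean of 14.54 (SD 0.45, n = 30) and was lower with high-dose pioglitazone (-0.52 ± 0.08, SE, adjusted p 7.25e-07) and rosiglitazone (-0.28 ± 0.08, adjusted p 0.017). Its low-dose value was -0.23 (adjusted p 0.0834), and the rosiglitazone call ended without vehicle replicate 1 (adjusted p 0.101) or 2 (0.0764). Its partner Rxra had mean signals of 8.34 with vehicle and 8.03, 8.22 and 8.16 with the treatments, and was not called.

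Of 34 genes of fatty acid oxidation, 3, 4 and 3 rose and 0 fell with the 3 treatments in the same order, and 5, 5 and 4 rose and 0, 0 and 1 fell adjusted over the list alone. Beside the Acaa1 pair, Acaa2, the mitochondrial thiolase, rose by 0.45, 0.49 and 0.35, and the peroxisome gene Pex11a rose by 0.42 with high-dose pioglitazone. The rosiglitazone call of Acaa2 ended without vehicle replicate 1 (adjusted p 0.0504) or rosiglitazone replicate 3 (0.0624). The list mean was 0.14, 0.13 and 0.11, with adjusted p 0.000967, 0.0017 and 0.0163, and 0.568, 0.655 and 0.84 with an estimated correlation. Acaa1a and Acaa1b, close in sequence, had the largest rises among its called members (1.25, 1.44 and 1.32 for Acaa1a). Whether their probes measure separate signals was not tested. If they do not, the list mean, its test and the counts of risen genes take in 1 signal more than once. The list was not tested without this pair. Of 37 oxidative phosphorylation genes 1 rose with each treatment and 0 fell, also when adjusted over the list alone. The gene was Uqcrc1 with low-dose pioglitazone (0.18) and Cycs, cytochrome c, with high-dose pioglitazone (0.33) and rosiglitazone (0.24). The Uqcrc1 call ended without vehicle replicate 1, 2 or 3 (adjusted p 0.142, 0.093 and 0.125) or low-dose replicate 1, 2, 3 or 4 (0.132, 0.0784, 0.166 and 0.112). The rosiglitazone call of Cycs ended without vehicle replicate 1 or 3 (0.162 and 0.0926) or rosiglitazone replicate 1, 2 or 4 (0.0565, 0.0631 and 0.0572). The list mean was 0.05, 0.07 and 0.07, with adjusted p 0.0489, 0.00027 and 0.000921, and 0.738, 0.598 and 0.707 with an estimated correlation. The low-dose list call also ended with the replicate block (camera adjusted p 0.0798), with 75th percentile centring (0.0712) and without the 2 arrays of low correlation (0.0964). Of 22 genes of fatty acid and sterol synthesis, 1, 0 and 1 rose and 1, 1 and 0 fell (adjusted p 0.436, 0.443 and 0.77), and 2, 0 and 2 rose and 1, 1 and 0 fell adjusted over the list alone.

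Genes that handle foreign compounds went both ways. Of the 24 tested on that list, 4, 4 and 5 rose and 1, 3 and 3 fell, and adjusted over the list alone 8, 5 and 8 rose and 2, 3 and 4 fell. The cytochrome P450 gene Cyp3a18 rose by 1.06, 0.91 and 1.0, and Hmox1, heme oxygenase, by 0.61, 0.66 and 0.79. Aldh1a1, which oxidises retinaldehyde, rose by 0.96, 1.03 and 0.99 (adjusted p 0.0478, 0.0157 and 0.023). Its calls were not checked with a replicate number left out. Cyp1a1, a P450 induced through the aryl hydrocarbon receptor, was 2.80-fold lower with high-dose pioglitazone (adjusted p 0.000227) and 2.30-fold lower with rosiglitazone (adjusted p 0.00423). Its low-dose difference was -0.88 (adjusted p 0.0833). Aldh3a1 fell by 0.77, 1.02 and 1.16. Por rose with rosiglitazone (0.34) and Gclc fell with high-dose pioglitazone (-0.37). The list's adjusted p was 0.0022, 0.0944 and 0.00947, and 0.568, 0.744 and 0.707 with an estimated correlation. The low-dose calls of Hmox1 and Aldh3a1 ended without vehicle replicate 1 (adjusted p 0.0608 and 0.0698) and without low-dose replicate 3 (0.0818 and 0.122). The Hmox1 call also ended without low-dose replicate 1 (0.075), and the Aldh3a1 call without vehicle replicate 3 (0.106) or low-dose replicate 4 (0.12).

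Genes of epithelial differentiation did not move as groups. Of 14 tested squamous differentiation genes, 1, 2 and 2 rose and 1, 2 and 2 fell with the 3 treatments, and adjusted over the list alone 2, 2 and 2 rose and 2, 2 and 2 fell. Ivl, involucrin of the cornified envelope, rose 2.05-fold, 2.29-fold and 2.46-fold (adjusted p 0.00191, 7.31e-05 and 1.15e-05), while Krt4 fell, and Krt1 fell by 0.70 with high-dose pioglitazone and 0.60 with rosiglitazone. Calml3 rose by 0.45 with high-dose pioglitazone (adjusted p 0.0287) and 0.57 with rosiglitazone. Of 23 umbrella cell and urothelial differentiation genes, 1, 1 and 1 rose and 0, 2 and 1 fell. Adjusted over the list alone, 2, 1 and 1 rose and 1, 2 and 1 fell. The falls called over all genes were those of Pparg, the drug target, which stands on this list, and of Foxa1. Pparg gave -0.52 with high-dose pioglitazone and -0.28 with rosiglitazone, and Foxa1 -0.42 with the high dose. Krt19 rose by 0.43, 0.34 and 0.46, and its pioglitazone calls ended without low-dose replicate 1 (adjusted p 0.0509), and without vehicle replicate 1 (0.0517) or high-dose replicate 1 (0.0575). Of 13 basal markers 0 rose and 1, 2 and 1 fell, and adjusted over the list alone 1, 0 and 1 rose and 2, 2 and 2 fell. Krt15 fell by 0.52 with high-dose pioglitazone and 0.50 with rosiglitazone. Cdh3 gave -0.58 and -0.80 with low- and high-dose pioglitazone (adjusted p 0.0365 and 0.000488). The adjusted p of these lists ranged from 0.217 to 0.982 with the preset correlation. Median, mean and test differed in sign for the squamous list with each treatment and for the basal list with low-dose pioglitazone and rosiglitazone.

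Leukocyte markers were lower with every treatment. Of 22 tested, 0 rose and 5, 9 and 7 fell with low-dose pioglitazone, high-dose pioglitazone and rosiglitazone, and adjusted over the list alone 1, 0 and 0 rose and 8, 11 and 11 fell. Cd74, the invariant chain of MHC class II, had a vehicle mean of 12.72 (SD 0.45, n = 30) and fell by 0.49, 0.67 and 0.46. Tyrobp, a signalling adaptor of myeloid cells, fell by 0.41, 0.49 and 0.45, and Coro1a by 0.40, 0.55 and 0.34. Fcer1g and Laptm5 fell with each treatment as well. Ptprc (CD45) and RT1-Da fell with high-dose pioglitazone and rosiglitazone, and Cd14 and Cd3d with high-dose pioglitazone (adjusted p 0.0137 and 0.0473). The rosiglitazone call of Ptprc ended without vehicle replicate 2 (adjusted p 0.0518) or rosiglitazone replicate 3 (0.0718). The list mean was -0.19, -0.26 and -0.24 (camera adjusted p 1.78e-05, 3.56e-07 and 6.69e-06). With an estimated correlation the adjusted p was 0.357, 0.0738 and 0.257. Without vehicle replicate 1 the Cd74 calls of low-dose pioglitazone (adjusted p 0.106) and rosiglitazone (0.0828) ended, as did the low-dose call without low-dose replicate 1 (0.0611) or 3 (0.0559). Without vehicle replicate 1 or 2 or low-dose replicate 1, 3 or 4 the low-dose call of Laptm5 ended (0.082, 0.0607, 0.109, 0.0579 and 0.0724). The low-dose call of Coro1a ended without vehicle replicate 1 (0.109) or 2 (0.0621) or low-dose replicate 1 (0.0778) or 4 (0.0506).

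Markers of other cell types that a scraping can hold were tested in the same way. The mean of the 21 fibroblast and matrix markers was -0.51, -0.12 and -0.41 with the 3 treatments (adjusted p 1.78e-05, 0.699 and 0.00434, and 0.568, 0.925 and 0.959 with an estimated correlation), and 0 single members were called. With the smooth muscle score as a covariate, added after the data had been seen, the mean was -0.325, -0.263 and -0.275. The high dose was then called as well (camera adjusted p 8.29e-05, 0.0127 and 0.0105). The mean of 14 smooth muscle markers was -0.48, 0.38 and -0.33 (adjusted p 0.0731, 0.199 and 0.488) and that of 14 adipocyte markers -0.24, 0.44 and 0.00 (0.404, 0.0233 and 0.926, the high-dose call being lost at 0.655 with an estimated correlation). In these 3 lists limma called 0 members adjusted over the list alone too. The mean of 7 erythrocyte markers was -0.41, -0.44 and -0.27 (0.0145, 0.0277 and 0.225, and 0.602, 0.743 and 0.981 with an estimated correlation), with Slc4a1, the red cell anion exchanger, called in each (-0.73, -0.81 and -0.68) and 1, 2 and 1 fallen adjusted over the list alone. Of 12 endothelial markers Cldn5 alone was called, with rosiglitazone (-0.71), also over the list alone. The low-dose call of Slc4a1 ended without vehicle replicate 1, 2 or 4 (adjusted p 0.0825, 0.0699 and 0.0573) or low-dose replicate 1, 3 or 4 (0.0561, 0.109 and 0.154). Its rosiglitazone call ended without vehicle replicate 1, 2 or 4 (0.0688, 0.0641 and 0.0692) or rosiglitazone replicate 1, 3 or 5 (0.0673, 0.0675 and 0.0533). That of Cldn5 ended without vehicle replicate 3 or 5 (0.0885 and 0.124) or rosiglitazone replicate 1 or 3 (0.106 and 0.0916). The endothelial adjusted p was 0.0766, 0.258 and 0.0273, and 0.707 for rosiglitazone with an estimated correlation. The 13 skeletal muscle markers had adjusted p 0.436, 0.543 and 0.74, with 0 called. The rosiglitazone value of the adipocyte list is one where median and mean differ in sign from the test.

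The remaining lists were not called, apart from inflammatory mediators with low-dose pioglitazone. Of 24 inflammatory mediators, 0 rose and 0, 1 and 1 fell (adjusted p 0.0489, 0.0968 and 0.488, and 0.568 for the low dose with an estimated correlation). Adjusted over the list alone 0, 1 and 2 fell. The gene that fell was the chemokine Ccl5, with high-dose pioglitazone (-0.86) and rosiglitazone (-0.59). The rosiglitazone call of Ccl5 ended without vehicle replicate 1 (0.0742) or 5 (0.0898) or rosiglitazone replicate 1 (0.0504) or 3 (0.17). Of 35 cell cycle genes 1, 1 and 0 rose and 0, 0 and 2 fell (adjusted p 0.828, 0.699 and 0.488), the same counts as over the list alone. Ccne1, cyclin E1, rose by 0.47 and 0.44 with the pioglitazone doses, and Foxm1, a regulator of mitotic genes, fell by 0.30 with rosiglitazone. The low-dose call of Ccne1 ended without vehicle replicate 2, 3 or 5 (adjusted p 0.0995, 0.0553 and 0.0607) or low-dose replicate 1, 3 or 4 (0.0963, 0.174 and 0.0964). Its high-dose call ended without vehicle replicate 2 or 5 (0.0963 and 0.0584) or high-dose replicate 1, 4 or 5 (0.0518, 0.059 and 0.112). The Foxm1 call ended without vehicle replicate 1 (0.133) or rosiglitazone replicate 3 (0.146) or 4 (0.117). Of 20 immediate-early and EGFR ligand genes 2, 0 and 2 rose and 0, 2 and 1 fell (adjusted p 0.828, 0.101 and 0.754), and over the list alone 3, 1 and 2 rose and 0, 5 and 2 fell. Myc fell by 0.36 with high-dose pioglitazone. Of 20 p53 targets 2, 0 and 1 rose and 0, 2 and 1 fell (0.369, 0.99 and 0.735), and over the list alone 2, 2 and 1 rose and 0, 3 and 3 fell. Of 22 water and ion transport genes 0, 0 and 1 rose and 1, 1 and 2 fell (0.885, 0.653 and 0.926), and over the list alone 1, 0 and 1 rose and 1, 1 and 2 fell. Median, mean and test differed in sign for water transport with the low dose and for the cell cycle and p53 lists with the high dose.

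**Figure D2:**
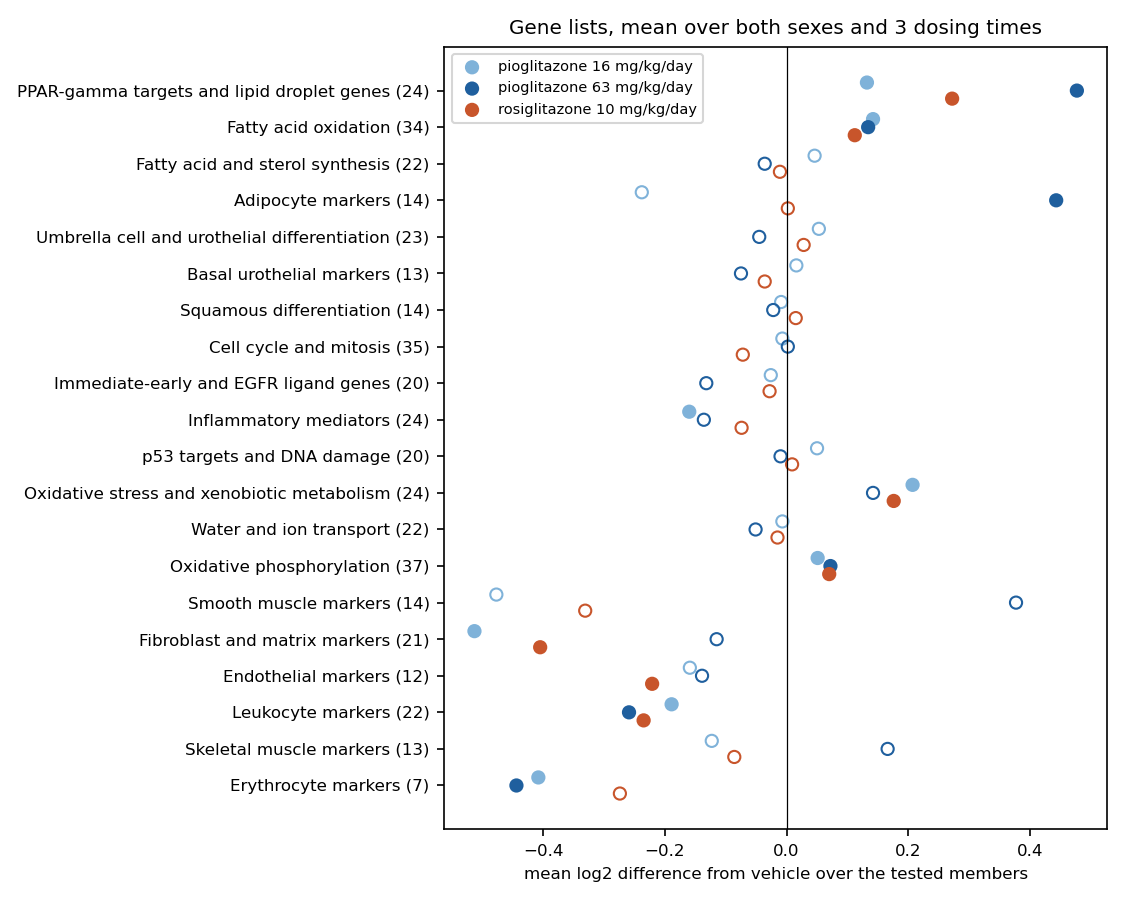
Mean log2 difference from vehicle over the tested members of each gene list (number in brackets) for the 3 treatments, filled where the camera adjusted p with the preset correlation was under 0.05. Leukocyte markers lay at -0.19, -0.26 and -0.24, while the smooth muscle mean was -0.48, 0.38 and -0.33.

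By limma's test of 12713 genes, low-dose pioglitazone changed 360 genes (202 higher, 158 lower), high-dose pioglitazone 837 (344 higher, 493 lower) and rosiglitazone 710 (315 higher, 395 lower), of which 15, 28 and 25 differed by 2-fold or more. Including the 3 arrays marked as failing quality control gave 62, 313 and 138 genes, and it ended the list calls of PPAR-gamma targets with the low dose (adjusted p 0.136) of fatty acid oxidation with both pioglitazone doses (0.279 and 0.254), of inflammatory mediators with the low dose (0.279) and of oxidative phosphorylation with each treatment (0.279, 0.254 and 0.148), whose mean turned to -0.08 and -0.12 with the pioglitazone doses. Leaving out low-dose replicate 1, 3, 4 or 5, or vehicle replicate 1 or 2, gave 120, 142, 133, 561, 156 and 227 genes for the low dose, high-dose replicate 3 gave 539 for the high dose, and vehicle replicate 1 or rosiglitazone replicate 3 gave 441 and 462 for rosiglitazone; without the 2 arrays of low correlation, chosen after seeing the data, the counts were 666 for the low dose and 1193 for rosiglitazone.

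Within single sexes and times, Rgs17 and Cpt1c stood out at 28 and 90 days. Rgs17 was higher by 2.68 in females and 2.40 in males after 90 days of low-dose pioglitazone, by 2.99 and 2.70 with the high dose and by 2.93 and 2.23 with rosiglitazone, each called. At 3 days its differences ran from 0.47 to 0.73, and 0 of the 6 were called. Cpt1c was called in all 4 groups at 28 and 90 days with high-dose pioglitazone (1.58 to 2.30) and with rosiglitazone (1.37 to 2.32). Acaa1a reached 1.93 in females at 28 days with rosiglitazone. Krt4 was lower by -2.79 ± 0.54 (SE) in males and -2.09 ± 0.54 in females after 90 days of the high dose (adjusted p 0.00134 and 0.0261). Akr1b8 was raised in males at 28 days, by 3.59, 3.66 and 4.72 with the 3 treatments (adjusted p 0.0357, 0.0127 and 0.000106). These differences use the same vehicle males, so they are not independent between treatments. The same holds for the other genes compared between treatments within a sex and time. Ttr was raised by 2.91 in males after 3 days of high-dose pioglitazone.

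These comparisons asked which genes respond in each sex at each time. In females at 3, 28 and 90 days limma called 0, 5 and 5 genes with low-dose pioglitazone, 1064, 8 and 153 with the high dose and 8, 46 and 312 with rosiglitazone. In males it called 2, 19 and 22, then 13, 27 and 79, and then 9, 134 and 4. The count of 0 had 1241 genes at an unadjusted p under 0.05, where chance gives 636. The 1064 genes of high-dose females at 3 days (211 higher, 853 lower) rest on replicate 3 of that group, whose median correlation with its group is 0.838: without it limma called 0 genes. The other counts of single groups also moved by over 1.5 times when a replicate number was left out, and their ranges are given with the alternatives.

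**Figure D3:**
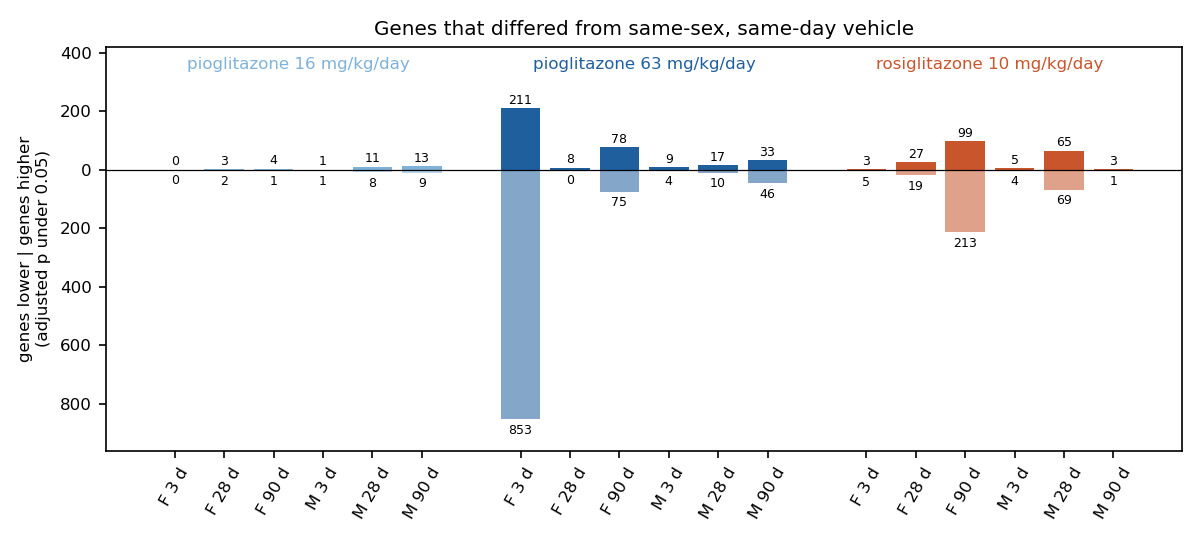
Number of genes higher (upward bars) and lower (downward bars) than vehicle of the same sex (F, M) and day at an adjusted p under 0.05, for each treatment. The bar of 211 and 853 genes in females after 3 days of high-dose pioglitazone rests on 1 array.

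The effects of dosing in females and males were then compared directly. Fabp4, Acaa1a and Rgs17 rose in the mean over both sexes, and no gene's rise or fall was shown to differ between the sexes. For low-dose pioglitazone, high-dose pioglitazone and rosiglitazone limma called 0, 0 and 0 genes, with 597, 976 and 695 at an unadjusted p under 0.05, where chance gives 636. Without the filter on low signal the counts were 7, 0 and 1.

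Whether effects changed with dosing time was tested across 3, 28 and 90 days, averaged over the sexes. Rgs17 differed by 0.60, 2.0 and 2.84 from vehicle with high-dose pioglitazone (SE 0.30, adjusted p 0.0143) and by 0.54, 2.1 and 2.58 with rosiglitazone (SE 0.28, adjusted p 0.0167). Calr, calreticulin of the endoplasmic reticulum, went from -0.99 through 0.51 to -0.18 with low-dose pioglitazone (adjusted p 0.0395), from -1.40 through 0.23 to 0.50 with the high dose (1.14e-05) and from -1.0 through -0.14 to 0.63 with rosiglitazone (0.00341). The treatments share the vehicle animals of each time, so the Calr results, like those of Rgs17, are not independent between treatments. With rosiglitazone Ahrr, the repressor of the aryl hydrocarbon receptor, gave -0.04, -0.47 and -2.12 (adjusted p 0.0246). The RNA helicase gene Ddx5 gave 0.35, -0.26 and -0.64, and the DNA helicase gene Recql5 0.43, 0.05 and -0.46. By limma's F test 1, 2 and 5 genes changed with time for the 3 treatments. Leaving out vehicle replicate 1, 2, 3, 4 or 5, or low-dose replicate 1, 2, 3 or 4, gave 0 genes for the low dose, vehicle replicate 1 or 2 gave 1 for the high dose, and for rosiglitazone vehicle replicate 2, 4 or 5 gave 0, 8 or 3 and rosiglitazone replicate 1, 4 or 5 gave 1, 2 or 10. Without the 2 arrays of low correlation the counts were 2, 4 and 42.

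Pioglitazone and rosiglitazone share the thiazolidinedione ring and differ in the side chain, which carries an ethyl-pyridine in pioglitazone and a methylamino-pyridine in rosiglitazone. They were given at different doses, so the values stand side by side at equal times and not at equal doses. No gene was shown to respond differently. Fabp4 differed by 0.24 (95 percent interval -0.05 to 0.52) between the pioglitazone doses and by -0.14 (-0.42 to 0.13) between rosiglitazone and high-dose pioglitazone. The corresponding values of Rgs17 were 0.24 (-0.10 to 0.57) and -0.07 (-0.41 to 0.26), and those of Acaa1a 0.19 (-0.03 to 0.41) and -0.12 (-0.34 to 0.10). Ivl gave 0.16 (-0.30 to 0.61) and 0.11 (-0.34 to 0.55), and Akr1b8 -0.09 (-0.76 to 0.59) and -0.04 (-0.70 to 0.62). The Krt4 interval excluded 0 for both differences, at -0.66 (-1.12 to -0.20) and 0.52 (0.07 to 0.97), with adjusted p 0.562 and 0.984. The differences between rosiglitazone and low-dose pioglitazone were 0.09 (-0.18 to 0.37) for Fabp4, 0.16 (-0.17 to 0.49) for Rgs17 and -0.14 (-0.59 to 0.31) for Krt4. Limma called 0 genes for high-dose against low-dose pioglitazone, 0 for rosiglitazone against the high dose and 0 against the low dose, with 1091, 387 and 432 at an unadjusted p under 0.05, where chance gives 636. Leaving out rosiglitazone replicate 4 gave 1 gene for rosiglitazone against the high dose. Among gene lists, the PPAR-gamma targets were 0.34 higher with the high than the low pioglitazone dose (adjusted p 4.22e-08, and 0.129 with an estimated correlation) and differed by -0.20 between rosiglitazone and the high dose (2.94e-05, and 0.377). Over the same pair of differences the smooth muscle markers moved by 0.85 and -0.71, the adipocyte markers by 0.68 and -0.44 and the fibroblast markers by 0.40 and -0.29, none of them called with an estimated correlation (lowest adjusted p 0.161).

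The treatments shared many of their genes. In all 3, 121 genes were higher and 106 lower, among them Fabp4, Acaa1a, Cpt1c, Rgs17 and Ivl on the higher side and Krt4, Pou3f1, Apoe and Gpt on the lower. Low- and high-dose pioglitazone shared 140 higher and 118 lower genes, against 5.47 and 6.13 for independent lists. The low dose and rosiglitazone shared 140 and 117 (5.01 and 4.91), and the high dose and rosiglitazone 215 and 257 (8.52 and 15.3). No gene was called in opposite directions. The treatments were compared with the same vehicle animals, and with these animals split between the treatments 65.7, 60.4 and 152 genes were shared on average. Across genes, which are not independent replicates, the differences from vehicle correlated at 0.603 for the 2 pioglitazone doses, 0.818 for the low dose and rosiglitazone and 0.769 for the high dose and rosiglitazone. Simulations of unchanged groups gave 0.456, 0.437 and 0.458 on average and up to 0.896, 0.875 and 0.898, above the observed values. With split controls the correlation was 0.429 ± 0.19, 0.599 ± 0.094 and 0.531 ± 0.14 (SD over 20 splits). The covariance was 0.0247, 0.0338 and 0.0316, against simulated means of 0.00972, 0.0082 and 0.0095 and highest simulated values of 0.044, 0.035 and 0.0424, which also lie above it.

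**Figure D4:**
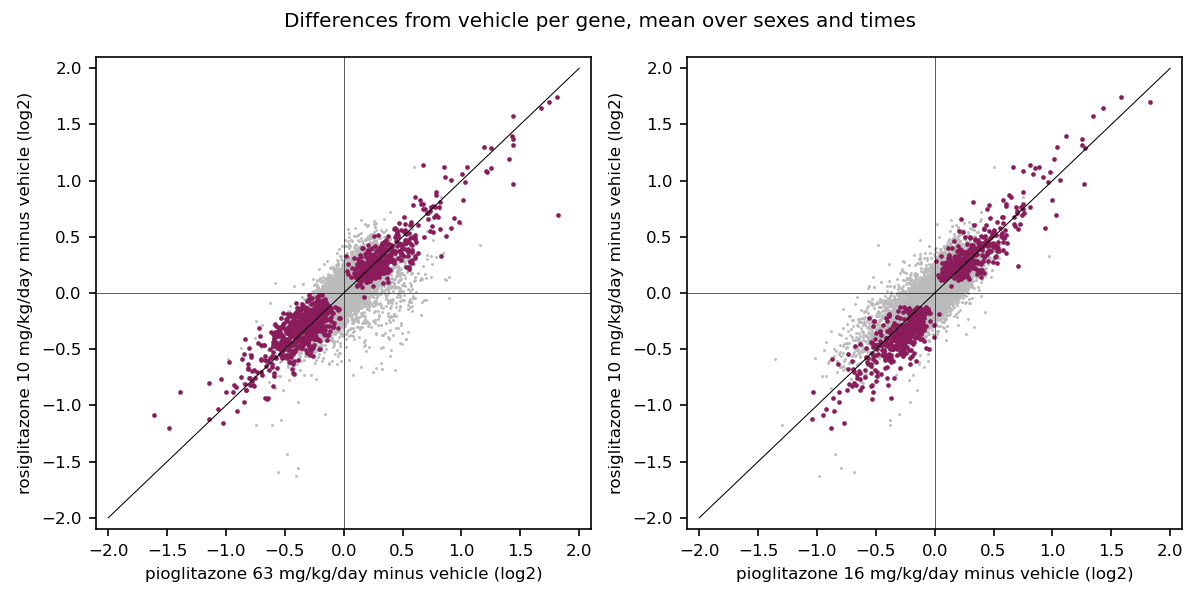
Log2 difference from vehicle per gene, rosiglitazone on the vertical axis against high-dose (left) and low-dose (right) pioglitazone on the horizontal axis, with genes called in at least 1 of the 2 treatments in purple and the line of equality in black. The correlations across genes are 0.769 and 0.818, with 0.531 and 0.599 on average when no vehicle animal is shared.

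Among vehicle animals, females and males differed most in secretoglobin genes, which code for small secreted proteins. Scgb1d2, Scgb1d4 and Scgb2a1 were lower in females (adjusted p 0.00437, 0.00538 and 0.0204), as were Andpro, named for its dependence on androgen (0.00437), and Wfdc3 (0.00538). Over all arrays the female medians were 4.28, 4.52, 4.83, 5.09 and 5.0 in that order, near the lowest signals, so the size of these differences is not given. The male signal was uneven, Scgb1d2 exceeding a log2 signal of 10 in 8 of 15 vehicle males. Higher in females were the X-linked genes Eif2s3 (0.59, adjusted p 5.18e-11) and Utx (0.66), the chemokine Ccl19 (0.94), Calml3 (0.85) and Gja4, a connexin of blood vessels (0.84). Limma called 19 genes, 8 higher and 11 lower in females; leaving out vehicle replicate 3, 4 or 5 gave 10, 2 or 9. Endothelial markers were higher in females (mean 0.42, adjusted p 8.57e-05), inflammatory mediators lower (-0.28, 0.000768) and PPAR-gamma targets higher (0.19, 0.00212), with adjusted p of 0.136, 0.136 and 0.648 with an estimated correlation.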

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

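For these results the tests chosen only after the result was seen are the leukocyte tests without 2 arrays and with the erythrocyte score, the smooth muscle covariate and the removal of high vehicle values for Cyp1a1, Ahrr and Aldh3a1, and the shares that a score can account for. These shares were defined after the slopes had been seen, and the removal of high vehicle values replaced a comparison of medians set beforehand, which reused the same vehicle animals for each treatment.

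Leukocyte markers were lower with all 3 treatments, by -0.19, -0.26 and -0.24 in the list mean, although with an estimated correlation the list was not called with any. The erythrocyte means were also below 0 (-0.41, -0.44 and -0.27), called with the pioglitazone doses and not with rosiglitazone (camera adjusted p 0.0145, 0.0277 and 0.225). With an estimated correlation the erythrocyte list was not called with any treatment either. The 2 arrays that correlate poorly with their own group are not the cause, since without them the highest adjusted p was 1.64e-05. Less tissue from beneath the urothelium, as measured by fibroblast markers, is argued against as the whole cause. With the fibroblast score as a covariate the leukocyte shift kept at least 100.9 percent of its size (105.7, 100.9 and 103.6, camera p at most 4.29e-06). At 2 SE of its slope within groups (-0.021 ± 0.027, SE) that score accounts for at most 9.2 percent of the fall. Both values rest on that slope, and tissue that the fibroblast markers do not follow is not covered. Less blood, as measured by red cell markers, is argued against as the whole cause too, with at least 97.2 percent kept (97.2, 97.8 and 98.5), a slope of 0.013 ± 0.031 and at most 17 percent accounted for. Fewer leukocytes in the treated bladder lining, or less expression of these genes in the cells present, may account for it and stays an untested hypothesis.

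Cyp1a1, Ahrr and Aldh3a1, known targets of the aryl hydrocarbon receptor, were lower with high-dose pioglitazone and rosiglitazone, while with the low dose Aldh3a1 was called and Cyp1a1 (-0.88, adjusted p 0.0833) and Ahrr (-0.52, adjusted p 0.084) were not. Carry-over of smooth muscle is argued against as the whole cause, since all 7 calls remained with the smooth muscle score as a covariate, and at 2 SE of the slopes within groups that score accounts for at most 5 percent of the fall of Cyp1a1, 5.6 percent for Ahrr and 9.1 percent for Aldh3a1. High values on a few vehicle arrays stay open for part of the pattern: without the highest vehicle value of each gene in each sex and time, which lowers the vehicle mean by construction, at least 69 percent of each called fall was kept and 5 of 7 calls remained, while those of Aldh3a1 with the low dose (adjusted p 0.134) and Cyp1a1 with rosiglitazone (0.0672) ended. Lower activity of the receptor could not be told from other causes: of 4 further targets Cyp1b1 was lower with rosiglitazone (-0.41, adjusted p 0.0491), but Nqo1, Ugt1a6 and Nfe2l2 were not called, and the 4 had means of -0.036, -0.147 and -0.082 (camera p 0.74, 0.168 and 0.448), too few genes to decide.

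Secretoglobin, Andpro and Wfdc3 signal appeared in part of the male arrays: Scgb1d2 exceeded a log2 signal of 10 in 18 of 57 male arrays, up to 18.33, and in 0 of 59 female arrays. By treatment these were 8 of 15 vehicle males, 4 of 13 and 5 of 14 with the pioglitazone doses and 1 of 15 with rosiglitazone, a difference that was not tested. Prostate or seminal vesicle tissue in the male scrapings may be a source, but of 10 listed genes of those glands 1 (Sbp, 8.32 in vehicle males against 5.26 in females) was higher in males, while Pbsn, at 4.97, and Svs4, at 5.12, lay near the lowest signals. Prostate lobes differ in the genes they express, so this 1 of 10 cannot decide, and expression in male urothelium itself stays open as an untested difference between the sexes.

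Arrays far from the others of their group were sought in 144 tests (24 groups and 6 measures), and 22 were found, where chance gives about 1 in 20. Arrays set apart by their median correlation with the own group (some other arrays have lower values) had 0.9841 (vehicle female day 28 replicate 2), 0.9788 (vehicle female day 90 replicate 4), 0.9519 (vehicle male day 3 replicate 3) and 0.858 (low-dose female day 28 replicate 5). In high-dose groups they were 0.8377 (female day 3 replicate 3), 0.9831 (female day 28 replicate 5), 0.9753 (female day 90 replicate 1) and 0.9212 (male day 28 replicate 4). The others were 0.9734 (low-dose male day 28 replicate 3), 0.953 (rosiglitazone female day 28 replicate 4) and 0.9343 (rosiglitazone male day 28 replicate 3). Fabp4 was lowest at 11.79 in vehicle male day 3 replicate 3, the next array being at 14.25. Rgs17 stood apart at 6.58 (vehicle male day 3 replicate 1), 9.92 (low-dose male day 28 replicate 4), 7.3 (high-dose male day 3 replicate 2) and 5.40 (rosiglitazone male day 3 replicate 5). Krt4 did so at 9.72 (vehicle male day 3 replicate 3), 12.15 (high-dose female day 28 replicate 4) and 11.54 (rosiglitazone female day 3 replicate 5). Ivl did so at 10.28 (vehicle female day 28 replicate 2), 6.93 (low-dose female day 28 replicate 5) and 9.90 (rosiglitazone female day 3 replicate 1).

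The effect of treatment differed between dosing times, by limma's F test, for 1 gene with low-dose pioglitazone, 2 with the high dose and 5 with rosiglitazone. The effects at 90 days were -0.183, 0.504 and 0.629 for Calr with the 3 treatments, 2.841 and 2.577 for Rgs17 with the high dose and rosiglitazone, and -2.121, -0.635 and -0.459 for Ahrr, Ddx5 and Recql5 with rosiglitazone. Among 7498 tested probes without a gene symbol, which enter no comparison of the report, 113, 207 and 330 differed from vehicle with the 3 treatments, of which 76, 108 and 152 were higher.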

How the results depend on the processing

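Tests chosen only after the results were seen are the fits without 2 arrays of low correlation and with the smooth muscle score as a covariate. Of 284 values of genes taken by the naming rule, to which the tallies of gene calls below refer, 145 were called. Of the called ones 49 lost the call without 1 replicate number. A change of direction was counted only for values called in the main fit or in the alternative, and 0 were found. Counts moved by over 1.5 times in 89 of 275 comparisons with the alternatives. The counts given below are those that moved, and all others that were run stayed within 1.5 times. The change with time was not run with only the compared groups in the fit. The cause of these moves was not tested, except where the construction of an alternative shows it. For gene lists the alternatives without the low-signal filter, with the mean of probes, with only the compared groups and with left-out replicates were not run.

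With the 3 failing arrays included the counts were 62 (low dose), 313 (high dose) and 138 (rosiglitazone), for low-dose females 0 (day 28) and 3 (day 90) and males 0 (day 3) and 1 (day 28). They were for high-dose females 4053 (day 3), 2 (day 28) and 11 (day 90) and males 3 (day 3), 3 (day 28) and 7 (day 90) and for rosiglitazone females 0 (day 3), 4 (day 28) and 17 (day 90) and males 1 (day 3), 3 (day 28) and 1 (day 90). They were for the change with time 0 (low dose), 1 (high dose) and 0 (rosiglitazone) and for vehicle females against males 6. The oxidative phosphorylation list mean turned to -0.08 with the low dose and -0.12 with the high dose. These arrays ended 58 calls of named genes and 7 of lists, the 2 whose direction turned among them.

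Without the filter on low signal, which tests more genes, the counts that moved were for high-dose males 16 (day 28), for the sex difference 7 (low dose) and 1 (rosiglitazone). They were for the change with time 0 (low dose) and for vehicle females against males 50. With quantile normalisation the count that moved was 0 for the change with time (low dose). With centring on the 75th percentile they were for low-dose females 3 (day 90), for high-dose females 5 (day 28). They were for rosiglitazone females 4 (day 3) and for the change with time 0 (low dose). With the mean of a gene's probes they were for low-dose females 3 (day 28) and males 1 (day 3), for rosiglitazone females 4 (day 3) and males 3 (day 3). With only the compared groups in the fit, which leaves fewer samples, they were 602 (low dose), for low-dose females 3 (day 28) and 13 (day 90) and males 0 (day 3), 9 (day 28) and 144 (day 90). They were for high-dose females 0 (day 3) and 113 (day 28) and males 0 (day 3), 6 (day 28) and 31 (day 90) and for rosiglitazone females 4 (day 3), 131 (day 28) and 44 (day 90) and males 0 (day 3) and 6 (day 28). They were for the difference between treatments 1 (high against low dose). Split vehicle animals gave fold-change correlations of 0.429 for the pioglitazone doses, 0.599 for the low dose with rosiglitazone and 0.531 for the high dose with rosiglitazone. Of the named genes 10 lost and 5 gained a call with only the compared groups, 6 lost and 3 gained with the mean of probes, 5 lost without the filter, 2 lost with the 75th percentile, and 2 lost and 1 gained with quantile normalisation. Of 60 list results 20 were weaker with an estimated correlation and 2 with the 75th percentile.

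With the replicate block the counts were 569 (low dose), for low-dose males 36 (day 28). They were for rosiglitazone males 3 (day 3) and for the change with time 11 (rosiglitazone). In this block the replicate numbers do not pair the animals, the design names no pairing, and 26 of 116 arrays correlated best with their own number. Among the 284 values of genes taken by the rule the block gave 7 calls more and 0 fewer, and among lists 1 call more and 1 fewer. Outside these values the block ended the high-dose call of Adipor2, and 8 leukocyte markers fell with the high dose against 9 without it. It was not run for vehicle females against males, where it is nested in sex.

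The next values come from the fits chosen after the data had been seen. Without the 2 low-correlation arrays the counts were 666 (low dose) and 1193 (rosiglitazone), for low-dose females 1 (day 3) and 1 (day 28) and males 39 (day 28). They were for high-dose females 0 (day 3) and 250 (day 90) and males 23 (day 3) and 123 (day 90) and for rosiglitazone females 27 (day 3), 86 (day 28) and 520 (day 90) and males 31 (day 90). They were for the change with time 2 (low dose), 4 (high dose) and 42 (rosiglitazone) and for vehicle females against males 29. With the smooth muscle score they were 1075 (rosiglitazone), for low-dose females 4 (day 3) and 21 (day 28) and males 30 (day 28) and 40 (day 90). They were for high-dose females 463 (day 3) and 313 (day 90) and for rosiglitazone females 142 (day 28) and males 4 (day 3), 233 (day 28) and 11 (day 90). They were for the change with time 4 (low dose) and 8 (rosiglitazone) and for vehicle females against males 48. Among the values of genes taken by the rule, 17 calls were gained without the 2 arrays and 22 with the smooth muscle score, and 0 were lost with either. Outside these values the high-dose call of Adipor2 ended without the 2 arrays, and 8 leukocyte markers fell with the high dose against 9 with them. Of lists 2 gained and 1 lost the call without the arrays, and 3 gained and 2 lost it with the score.

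Leaving out each replicate number of a treatment in turn (leave-one-out), which removes up to 6 arrays at a time, gave these ranges of genes called. The range was, for the means, 120 to 561 (low dose), 539 to 975 (high dose) and 441 to 679 (rosiglitazone). It was for low-dose females 0 to 9 (day 3), 0 to 23 (day 28) and 2 to 6 (day 90) and males 0 to 5 (day 3), 8 to 25 (day 28) and 9 to 26 (day 90). It was for high-dose females 0 to 2653 (day 3), 4 to 9 (day 28) and 84 to 162 (day 90) and males 3 to 66 (day 3), 11 to 27 (day 28) and 39 to 116 (day 90). It was for rosiglitazone females 0 to 76 (day 3), 8 to 85 (day 28) and 140 to 464 (day 90) and males 0 to 86 (day 3), 25 to 208 (day 28) and 1 to 7 (day 90). It was for the sex difference 0 to 0 (low dose), 0 to 0 (high dose) and 0 to 0 (rosiglitazone). It was for the change with time 0 to 1 (low dose), 1 to 3 (high dose) and 0 to 10 (rosiglitazone). It was for vehicle females against males 2 to 14. It was for the difference between treatments 0 to 0 (high against low dose), 0 to 1 (rosiglitazone against high dose) and 0 to 0 (rosiglitazone against low dose). The 1 gene between rosiglitazone and the high dose appeared without rosiglitazone replicate 4, and the 0 for high-dose females at 3 days without replicate 3.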

Other observations

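Genes of the aryl hydrocarbon receptor response were lower than vehicle in single groups at 90 days, given here as log2 differences. The treatments share the vehicle animals of each sex and time, so their values are not independent. High vehicle values, left open above for part of this pattern, were not examined within single groups. Cyp1a1 gave -3.21 ± 0.71 (SE) in females after 90 days of high-dose pioglitazone (adjusted p 0.00595) and -3.46 ± 0.71 after 90 days of rosiglitazone (adjusted p 0.00169). Ahrr gave -2.30 and -2.69 in the same groups, and Aldh3a1 -2.50 and -1.96. In males after 90 days of the high dose Ahrr gave -1.82 (adjusted p 0.0156) and Aldh3a1 -2.13 (adjusted p 0.00951). At 3 days Ahrr was -1.61 in high-dose females (adjusted p 0.0191), a group whose count of genes rests on replicate 3. Whether effects changed with time was called for Ahrr with rosiglitazone and not for the other 2 genes.

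Replicate numbers did not pair the samples. Arrays of the same number in different treatments of 1 sex and time, after the group means had been taken out, correlated at a median of 0.0284 over 168 pairs (lowest -0.683, 46.4 percent over 0.1). Those of different numbers did so at -0.00416 over 672 pairs, and 26 of 116 arrays correlated best with an array of their own number.

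Counts of genes were set beside those from other splits of the same animals, tests chosen only after the counts had been seen. For each, 100 splits were counted, the real one included, and chance is called excluded where under 5 of them gave as many genes. The lowest share that can be reached is 1 of 100. Of 31 counts 24 were over 0, and among 24 about 1.2 would pass that bound by chance. For the means over sexes and times, 1 split (the real one) gave as many genes for low-dose pioglitazone (360, highest other 0), high-dose pioglitazone (837, highest other 6) and rosiglitazone (710, highest other 422), so chance can be excluded. With low-dose pioglitazone it can be excluded for males at 90 days (1 split, 22 genes, highest other 5). With the high dose it can be excluded for females at 28 days (1, 8, 1), females at 90 days (1, 153, 4) and males at 90 days (1, 79, 4). With rosiglitazone it can be excluded for females at 28 days (1, 46, 2) and 90 days (1, 312, 23). It can be excluded for vehicle females against males (1, 19, 1). Low-dose females at 90 days (1, 5, 2) and rosiglitazone females at 3 days (1, 8, 5) and males at 90 days (1, 4, 1) met the bound with few genes. With a replicate number left out these counts ran from 2 to 6, 0 to 76 and 1 to 7, so they are not relied on. For the change with time with the high dose (1, 2, 1) and rosiglitazone (1, 5, 1) the bound was met too. Those splits exchange treated and vehicle animals within each sex and time. They ask whether treatment had any effect and not whether a steady effect changed, so they do not decide on a change with time.

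For 3 low-dose counts the bound was met although another split gave as many genes or more, so they are not relied on: females at 28 days (2 splits, 5 genes, highest other 5), males at 28 days (2, 19, 20) and the change with time (2, 1, 3), whose 1 gene was also lost in most leave-outs. Chance cannot be excluded for low-dose males at 3 days (24 splits, 2 genes, highest other 2535), high-dose females at 3 days (16, 1064, 3942), high-dose males at 3 days (6, 13, 133) and 28 days (9, 27, 511), and rosiglitazone males at 3 days (5, 9, 883) and 28 days (7, 134, 460). Counts of 0 are reached by every split, so for them the 100 of 100 splits decide nothing: low-dose females at 3 days (0 genes, highest other 1719), the differences between sexes (0 genes each, highest other 0, 408 and 9) and those between treatments (0 genes each, highest other 0, 9 and 86). Splits that call several times the real count point to a structure of the samples, which single outlying arrays can also give, and what those splits share was not tested.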
